A study of Mus musculus with 7 samples.

How the data were processed

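RNA of mouse bone marrow hematopoietic stem cells (HSCs) was measured by paired-end sequencing in 7 libraries. The labels give 3 libraries of cells with floxed Fth1 (called control here) and 4 of cells with deleted Fth1 (Fth1-deleted), all from mice aged 2 months. Per the labels, polyA RNA was used, and libraries were made with the NEBNext Ultra RNA kit from 1 µg of RNA each. The markers of the sort, the sex of the mice, the exons removed and the strand setting of the counting are not stated in the labels. The series text says that cells came from mice, but the labels do not say that each library came from a separate mouse. The p values here therefore measure spread between libraries.

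According to the series text, the authors aligned reads to GRCm38 with HISAT2 2.0.4 and counted reads per gene with HTSeq 0.9.1. The deposited values are FPKM, which the authors calculated from the gene length and the reads counted per gene, with no further scaling between libraries stated. The annotation release and any filter of the authors are not stated. The table holds 55855 gene identifiers, of which 55394 were matched to symbols and positions of GENCODE mouse release 21 (M21). Of the 461 unmatched identifiers, 282 are the authors' own identifiers, and 238 of these had enough signal to be tested. Coordinates are those of GRCm38, and the number after a library's group is its replicate number.

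Depth was read back from the values. FPKM multiplied by the mean transcript length fell on multiples of a fixed step in each library, and the step gave the number of counted reads. These were 13882463, 15046058 and 12058392 in the control libraries and 15453168, 13618724, 12806902 and 14800042 in the Fth1-deleted libraries. Of the values worth fewer than 50 reads, 98.8% to 99.4% were whole read numbers within 0.05 reads. A gene of 1 kb with a single read has an FPKM of 0.0647 to 0.0829. Where a group was at 0 in every library, its level was bounded at 3 reads per library, and folds against it are given as lower bounds. Such floors cover counting error only, since reads copied by PCR are not independent molecules. Among genes with over 100 reads on average, the median coefficient of variation was 31.1% between control libraries and 26.0% between Fth1-deleted libraries. Counting alone would give 3.87% and 3.82%.

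Values were analysed as log2(FPKM + 1). The 13948 genes with a mean FPKM of at least 1 over the 7 libraries were tested with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided, no covariate), and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 differences are Fth1-deleted minus control on the log2(FPKM + 1) scale, with their standard error (SE), and FPKM are given as mean ± SD. Single measures were compared by a two-sided exact permutation test over the 35 splits of the libraries into 3 and 4, whose smallest possible p is 0.0286. Gene lists were tested with limma's camera, a test of a list against all other tested genes, with a preset correlation of 0.01 between genes. Its p values were adjusted over the 34 lists. Camera was repeated with a correlation estimated for each list. Limma's fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, was run as another alternative.

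The samples, the tests, the 34 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Fth1 and then genes past the threshold whose groups do not overlap and whose higher group has a mean FPKM of at least 5. It takes up to 15 per direction by log2 difference, leaving out unnamed models, which are symbols of Gm or RP followed by digits, symbols ending in Rik or -ps, and bare accessions. It adds for each list up to 4 members past the threshold, or the 2 members with the smallest p where none passed. Finally it adds 20 fixed genes of iron handling, stem cells and cell division: Ftl1, Tfrc, Slc40a1, Hmox1, Ncoa4, Ireb2, Aco1, Gpx4, Slc7a11, Cdkn1a, Cdkn1c, Mki67, Mecom, Procr, Slamf1, Kit, Ly6a, Cd34, Cd48 and Flt3. Slc7a11 had a mean FPKM of 0.335 and was not tested. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule names are counted but not reported here by name.

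The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean FPKM of 5, size factors by median of ratios, quantile normalization, rescaling of FPKM to a fixed sum per library (TPM), limma without a trend, library weights (arrayWeights), the replicate number as a block, each library left out, a minimum absolute log2 difference of 1, limma's treat against 0.26, camera with an estimated correlation and fry. Others, chosen after seeing the data, were protein-coding genes alone, a ribosomal RNA covariate, the 5 libraries with high ribosomal RNA, a term for libraries with Y-linked reads, the 5 libraries with low mt-Co2, and limma-voom on the recovered reads.

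The tests were tried on simulated data with the means, depths and spread of the libraries, over 13707 genes in 10 runs with 200 changed genes each. Genes changed 2-fold were called in 13.6% of cases, 4-fold in 46.9% and 8-fold in 66.7%, and 0.0332% of unchanged genes were called. A list of 30 genes raised 1.5-fold was called in 10 of 10 runs and an unchanged list in 0 of 10. Genes were drawn independently there, so the list result holds for genes without correlation. Similar genes were searched with BLAST 2.17.0 among the annotated transcripts of M21, at 95% identity or more. The search covered named genes, mitochondrially encoded protein genes and genes with a mean FPKM of at least 20. Pairs at 98% identity over 80% of the length were called near-identical. Values were also handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and drawn with Matplotlib 3.10.9. All 7 libraries were kept. Reads per exon or base were not analysed here.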

Results

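Gene expression was measured in HSCs from control bone marrow (n = 3 libraries) and from Fth1-deleted bone marrow (n = 4 libraries), to ask what the loss of ferritin heavy chain, the iron-oxidizing subunit of the ferritin storage shell, changes in these cells. Counted reads ranged from 12058392 to 15453168 per library, and 13320 to 14882 genes had a value above 0. Across genes, the correlation was 0.826 to 0.850 between control libraries and 0.872 to 0.910 between Fth1-deleted libraries. Between groups it was 0.825 to 0.868, so control libraries were no more alike than libraries of different groups. Genes are not independent replicates here. On the first principal component, the main axis of variation (23.2% of the variance), control 2 was at -101 and the others at -15.1 to 39.4.

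Fth1 itself (ENSMUSG00000024661, chromosome 19, 9980598 to 9985098, plus strand) was lower in each Fth1-deleted library than in each control library. Its FPKM was 552, 659 and 638 in the control libraries and 202, 333, 358 and 114 in the Fth1-deleted libraries, so that 40.8% of the mean control level was still counted. The log2 difference was -1.42 (SE 0.33, limma adjusted p = 0.193 by Benjamini-Hochberg), and the exact permutation test gave p = 0.0571, so neither test passed its threshold. With a term for Y-linked reads, chosen after seeing the data, the log2 difference was -1.74 (SE 0.28) and the adjusted p 0.0491, where all alternatives gave 0.0491 to 0.684. Within control only control 2 had Y-linked reads, and within Fth1-deleted only Fth1-deleted 4 lacked them, so the term rests on these libraries. Control 2 was also the only control with a high share of ribosomal RNA reads. The remaining Fth1 reads cannot be assigned to exons from gene-level values.

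Fth1-deleted HSCs had more RNA of Hmox1, the enzyme that breaks down heme and releases its iron, and less of Txnip, an inhibitor of thioredoxin. Hmox1 rose 4.59-fold, from 22.1 ± 4.58 to 102 ± 30.3 FPKM (adjusted p = 0.0213). Txnip was 2.16-fold lower, at 842 ± 142 and 390 ± 8.93 (adjusted p = 0.0318). Both differences were seen in all 4 Fth1-deleted libraries against all 3 control libraries, which for Txnip the naming rule requires. The groups also differed in their share of ribosomal RNA reads (exact permutation p = 0.0286). Each of these genes kept its call in 9 of 23 alternatives. The calls were lost with any 1 library left out and with the ribosomal RNA covariate.

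**Figure D1:**
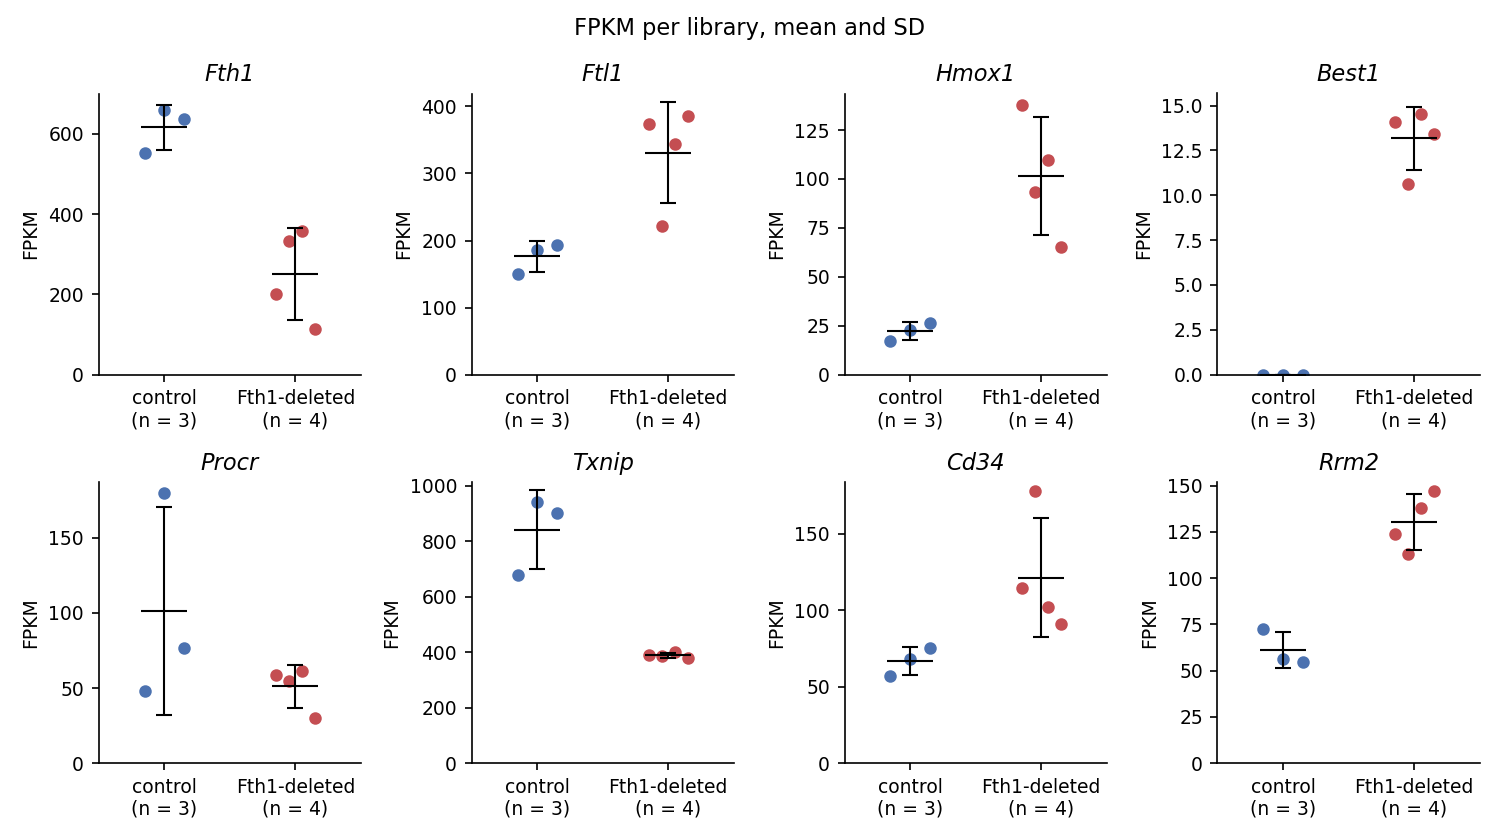
FPKM of 8 genes in each library (points), with the group mean and SD (lines), for 3 control and 4 Fth1-deleted libraries. Hmox1 had a mean of 22.1 in control and 102 in Fth1-deleted libraries; limma adjusted p values of Fth1, Ftl1, Procr, Cd34 and Rrm2 (0.193, 0.219, 0.540, 0.326 and 0.0918) did not pass the threshold.

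In all, 8 genes passed the threshold (limma, Benjamini-Hochberg), 4 higher and 4 lower. Hmox1 (ENSMUSG00000005413) lies on chromosome 8 from 75093621 to 75100589 and had a log2 difference of 2.12 (SE 0.28). Best1 (ENSMUSG00000037418, chromosome 19, 9985174 to 10001633, minus strand), which encodes a chloride channel best known from the retina, was at 0 in the 3 control libraries and at 13.2 ± 1.76 FPKM in the Fth1-deleted libraries, worth 198 to 298 reads each. That is at least 81.4-fold higher against 3 reads per library (adjusted p = 0.0260). Its annotated end lies 75 bp from the end of Fth1 on the opposite strand, and the strand setting of the counting is not known. Txnip (ENSMUSG00000038393) lies on chromosome 3 from 96557957 to 96561883 and had a log2 difference of -1.10 (SE 0.16).

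Non-coding genes were called as well. Snord49a (ENSMUSG00000065734, chromosome 11, 62603450 to 62603521), a small nucleolar RNA that guides RNA modification, was at 0 in control and at 46.8 ± 31.3 FPKM in Fth1-deleted libraries, worth 16 to 78 reads each. That is at least 15.2-fold higher against 3 reads per library (adjusted p = 0.0113). Snord73a (ENSMUSG00000064984, chromosome 3, 86138791 to 86138858) was at 0.706 ± 1.22 and 38.2 ± 11.7 FPKM (adjusted p = 0.0113). Their host genes, 2410006H16Rik and Rps3a1, had log2 differences of -0.17 (SE 0.24) and -0.20 (SE 0.18). Snord49a and Snord73a, of 72 and 68 bases, lie within these hosts, and the libraries were made from polyA RNA. Gene-level values do not show whether their reads come from the small RNAs or from host RNA, so their levels are uncertain. Both lost their call with the ribosomal RNA covariate and with limma-voom, settings chosen after seeing the data. The summed FPKM of all small nucleolar RNA genes was 668 ± 443 in control and 764 ± 240 in Fth1-deleted libraries (exact permutation p = 0.686). A pair of called genes fell outside the rule and are named after their values were seen. Gm7536 (ENSMUSG00000057036, chromosome 3, 24333068 to 24333511), a processed pseudogene, was lower with a log2 difference of -1.41 (adjusted p = 0.0121). Its 444 bases are 100% identical to the ribosomal protein gene Rpl27a, so its level is uncertain, and the sum of both genes was 1678 ± 280 and 1353 ± 233 FPKM (exact permutation p = 0.257). Gm19590 (ENSMUSG00000107061, chromosome 5, 75833035 to 75835645), a long intergenic RNA, was lower at 215 ± 37.8 and 67.5 ± 15.6 FPKM (adjusted p = 0.0213).

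The 32 genes of the hematopoietic stem cell list were lower as a group. The median log2 difference was -0.54, and 27 of 32 were negative (camera adjusted p = 1.76e-08; adjusted p = 0.296 with an estimated correlation). Over all genes 0 rose, 1 fell and 31 did not pass, and adjusted over the list alone 0 rose, 7 fell and 25 did not pass. Members chosen by their values include the transcription factors Hlf (206 ± 53.6 and 91.6 ± 27.2 FPKM) and Nkx2-3 (45.2 ± 6.94 and 19.3 ± 4.69), the guidance receptor Robo4 (25.6 ± 2.25 and 10.5 ± 2.13), Clec1a (15.1 ± 8.98 and 2.55 ± 1.21) and the cytokine gene Ltb (131 ± 54.1 and 68.8 ± 8.18). The share of ribosomal RNA reads was higher in the same 4 libraries than in control (exact permutation p = 0.0286). Surface markers fixed for description had log2 differences of -0.81 (SE 0.40) for Procr, -0.41 (SE 0.20) for Kit, -0.55 (SE 0.31) for Ly6a and 0.46 (SE 0.52) for Slamf1, none of them past the threshold. Mecom, a transcription factor of stem cells, had a log2 difference of -0.22 (SE 0.40), and Cdkn1c, a cell-cycle inhibitor of quiescent stem cells, -0.14 (SE 0.52).

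Genes of progenitors were higher as a group by camera. List means per library overlapped between the groups for multipotent progenitors (exact permutation p = 0.0857) but not for the neutrophil list (exact permutation p = 0.0571). The list of multipotent progenitors and lymphoid priming had a median log2 difference of 0.95 over 12 genes, or 0.62 without control 1, with 8 of them positive (camera adjusted p = 0.000854; adjusted p = 0.296 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 4 rose, 0 fell and 8 did not pass. Among the 5 libraries with low RNA of the mitochondrial gene mt-Co2, a subset chosen after seeing the data, the call ended at a median of 0.48. Those that rose include the lymphoid polymerase Dntt (1.46 ± 1.58 and 11.3 ± 6.72 FPKM), Cd34 (66.7 ± 9.32 and 121 ± 38.9) and Cd48 (12.4 ± 10.5 and 33.5 ± 15.2). Flt3, the receptor of lymphoid-primed progenitors, was at 7.04 ± 5.97 and 13.8 ± 5.62 (adjusted p = 0.579). The neutrophil and myeloid progenitor list was higher by a median of 1.31 over 14 genes, 11 of them positive (camera adjusted p = 0.000854; adjusted p = 0.296 with an estimated correlation). The call ended in the same subset, at a median of 1.36. The median was 0.68 with pseudocount 5, and reached 2.79 over all alternatives. Over all genes 0 passed, and adjusted over the list alone 1 rose, 0 fell and 13 did not pass: Mpo, the myeloperoxidase of granule precursors, at 2.07 ± 1.70 and 64.5 ± 56.1 FPKM. Ly6c2 was at 1.89 ± 3.27 and 13.2 ± 9.46. The most abundant members in control were Prtn3 and Lyz2, with log2 differences of -0.06 (SE 0.33) and -0.39 (SE 0.21), named after their values were seen.

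The B cell list was higher, with 12 of 12 genes positive and a median log2 difference of 1.28 (camera adjusted p = 0.00108, and 0.306 with an estimated correlation). The median was 3.16 with the 6 genes at 0 in control set at their bound, and 0.46 to 3.17 over all alternatives. No gene of the list passed over all genes, and adjusted over the list alone 1 rose, 0 fell and 11 did not pass. Vpreb1, a part of the surrogate light chain of B cell precursors, was at 0 in control and at 18.8 ± 14.0 FPKM, at least 50.04-fold higher against 3 reads per library. It shares 69.9% of its length with Vpreb2 at 97.6% identity. Igll1, the partner of Vpreb1, was at 0 and 7.57 ± 8.81. Immunoglobulin genes took 0.00166%, 0.000279% and 0.107% of reads in control and 0.179%, 0.00208%, 0.135% and 0.543% in Fth1-deleted libraries (exact permutation p = 0.229). The mast cell and basophil list was higher with 6 of 6 positive and a median of 0.83, or 1.04 with 1 gene at its bound and 1.31 without Fth1-deleted 2 (camera adjusted p = 0.0243; adjusted p = 0.296 with an estimated correlation). The call ended without control 2 (median 1.07), control 3 (0.59), Fth1-deleted 3 (0.75) or Fth1-deleted 4 (0.41), with the replicate block or a ribosomal RNA covariate, and among the libraries with high ribosomal RNA or low mt-Co2. Over all genes 0 passed, and adjusted over the list alone 1 rose and 5 did not pass: Cpa3, a mast cell protease, at 2.18 ± 3.78 and 26.8 ± 9.47 FPKM. Hdc was at 0.487 ± 0.843 and 3.95 ± 4.43.

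**Figure D2:**
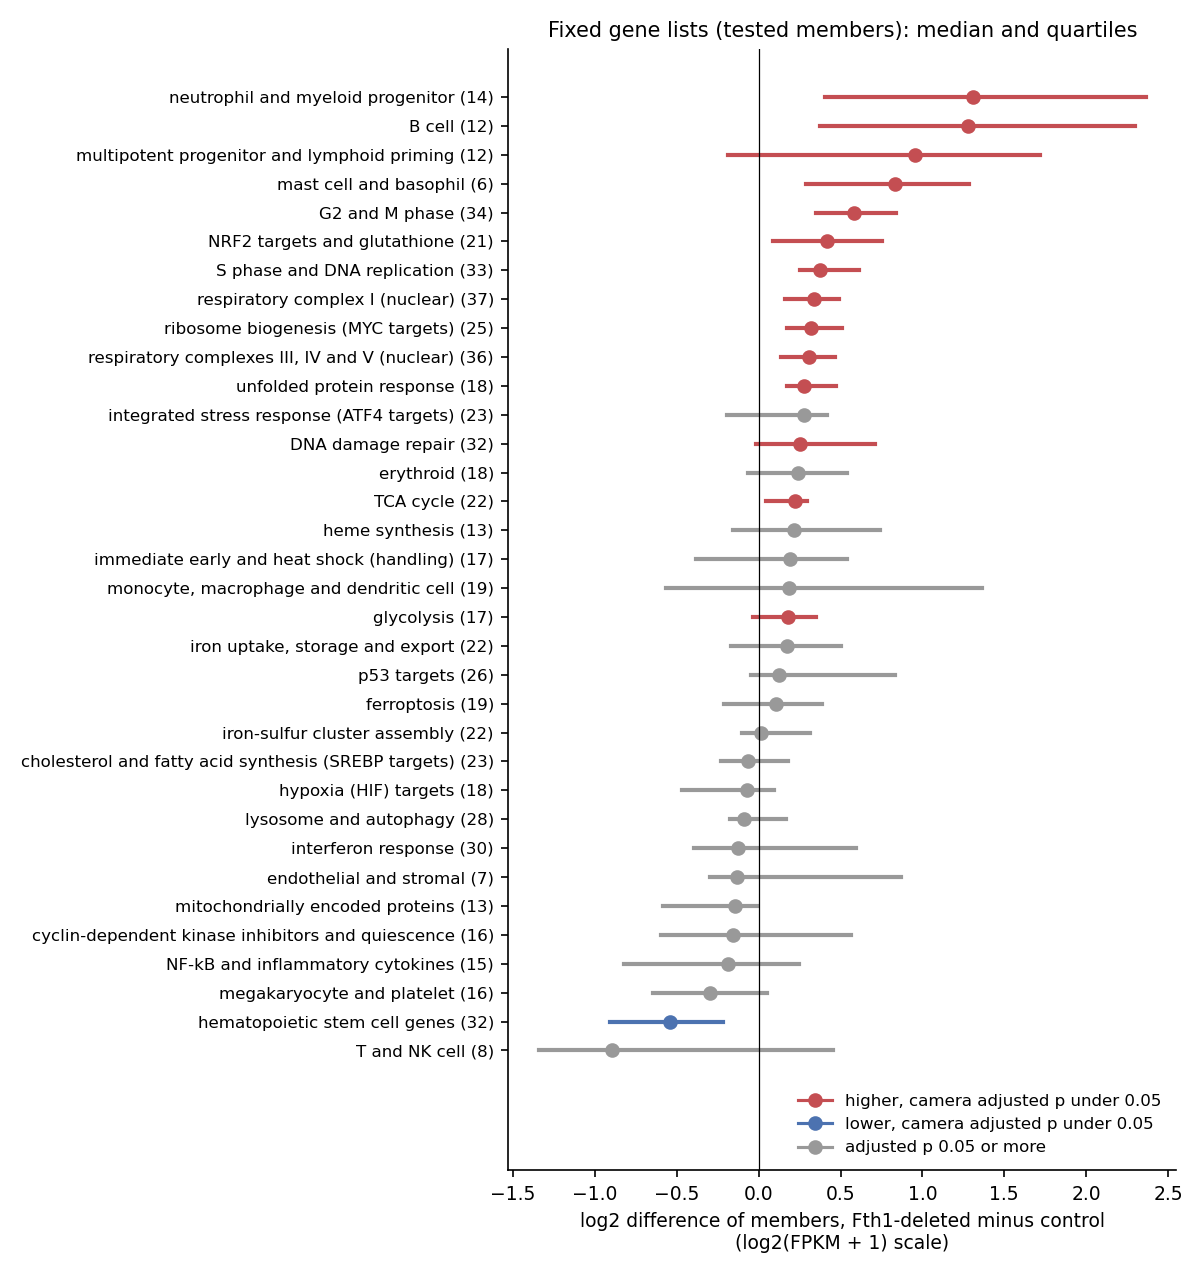
Log2 difference (Fth1-deleted minus control) of the members of each of the 34 lists, with the median (point) and quartiles (line), and the number of tested members in brackets. The hematopoietic stem cell list had a median of -0.54 and the G2 and M phase list of 0.58; colours give the camera call with the preset correlation, and 0 of the 15 calls hold with an estimated correlation.

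Genes of cell division were higher as a group. The list of G2 and M phase had a median log2 difference of 0.58, with 32 of 34 genes positive and a median of 0.27 without control 2 (camera adjusted p = 2.14e-09; adjusted p = 0.306 with an estimated correlation). None passed over all genes, and adjusted over the list alone 2 rose, 0 fell and 32 did not pass: Hmmr (13.5 ± 1.79 and 31.3 ± 4.39 FPKM) and Cdca3 (38.0 ± 8.18 and 69.6 ± 5.31), both acting in mitosis. Mki67, a marker of dividing cells, was at 78.1 ± 36.8 and 120 ± 9.84 (adjusted p = 0.435). The list of S phase and DNA replication had a median of 0.37, with 31 of 33 positive (camera adjusted p = 1.65e-08; adjusted p = 0.296 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 1 rose, 0 fell and 32 did not pass: Rrm2, a subunit of ribonucleotide reductase, at 61.1 ± 9.92 and 131 ± 15.1 FPKM. Mcm10 was at 15.5 ± 13.5 and 43.9 ± 13.4. Control libraries differed among themselves, with mean log2(FPKM + 1) of the G2 and M phase list at 5.55, 4.50 and 4.93 against 5.52, 5.61, 5.44 and 5.74 in Fth1-deleted libraries (exact permutation p = 0.0857). The S phase list was at 5.90, 5.52 and 5.85 against 6.28, 6.16, 6.15 and 6.26 (exact permutation p = 0.0286, the smallest possible; 0.139 adjusted over the 34 lists).

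The DNA damage repair list was higher with a median of 0.25, or 0.12 without control 2, and 24 of 32 genes positive (camera adjusted p = 0.00232; adjusted p = 0.306 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The checkpoint kinase gene Chek1 was at 18.5 ± 1.37 and 30.9 ± 5.16 FPKM. The ribosome biogenesis list was higher with a median of 0.32 and 23 of 25 positive (camera adjusted p = 8.37e-06; adjusted p = 0.357 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Nop58 was at 119 ± 9.85 and 184 ± 18.7 and Tcof1 at 55.0 ± 4.60 and 83.3 ± 9.29. The list of cyclin-dependent kinase inhibitors and quiescence was not called (adjusted p = 0.255). Its signs differ, with a median of -0.16 (-0.34 to -0.097 with 1 library left out), a mean of 0.02 and a camera direction of down. Of its 16 genes 0 rose and 1 fell over all genes (Txnip), and adjusted over the list alone 2 fell and 14 did not pass. The second was the immediate early gene Egr1, at 57.2 ± 38.7 and 17.5 ± 4.92. The p53 target list was not called either (26 genes, median 0.13, adjusted p = 0.0783), except without control 2 (median 0.44), with arrayWeights and with the replicate block, with 0 members past the threshold over all genes or adjusted over the list alone. Among its members, Cdkn1a, which arrests the cell cycle, was at 2.07 ± 2.07 and 8.84 ± 6.73 (adjusted p = 0.450), Mdm2 at 30.9 ± 1.48 and 59.0 ± 16.4 and Psrc1 at 22.9 ± 12.2 and 42.8 ± 6.10.

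**Figure D3:**
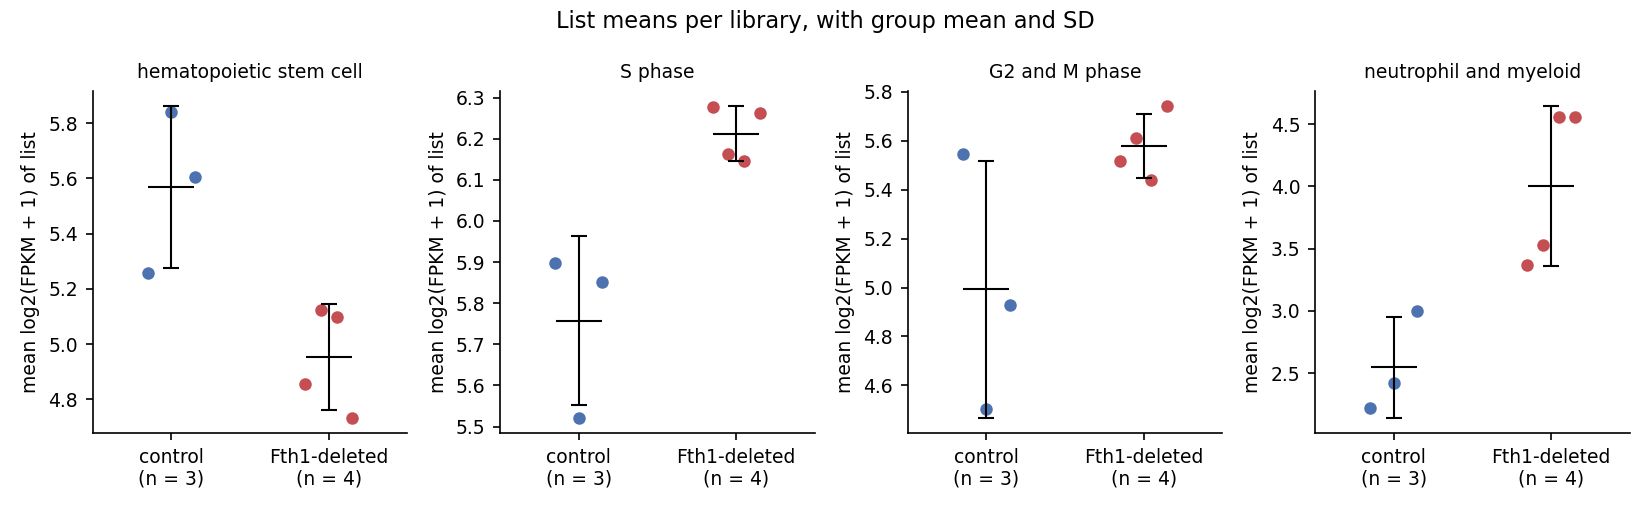
Mean log2(FPKM + 1) of 4 lists in each library (points), with the group mean and SD (lines), on axes that do not start at 0. The stem cell list separates the groups, with exact permutation p = 0.0286 (0.139 adjusted over the 34 lists), while control replicate 1 (5.55) lies among the Fth1-deleted libraries (5.44 to 5.74) for G2 and M phase.

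Among genes of redox defence, the list of NRF2 targets and glutathione was higher with a median of 0.42 and 17 of 21 genes positive (camera adjusted p = 1.43e-05; adjusted p = 0.296 with an estimated correlation). Over all genes 1 rose (Hmox1), 0 fell and 20 did not pass, and adjusted over the list alone 4 rose and 17 did not pass. The other 3, chosen by their values, were Gclm, the modifier subunit of glutathione synthesis (77.0 ± 10.6 and 148 ± 32.7 FPKM), thioredoxin Txn1 (149 ± 30.7 and 254 ± 53.9) and Pgd, an enzyme that makes NADPH (71.8 ± 17.8 and 120 ± 12.1). The iron uptake, storage and export list was not called (22 genes, median 0.17, adjusted p = 0.123), and without control 3 its median was -0.063. Over all genes 1 rose, 0 fell and 21 did not pass, and adjusted over the list alone 2 rose (Hmox1 and Ftl1) and 20 did not pass. Ftl1, the light chain of ferritin, was at 177 ± 23.2 and 331 ± 75.2 FPKM (adjusted p = 0.219, and 0.0159 adjusted over the list alone), and its value is uncertain since it is 99.6% identical to the pseudogene Ftl1-ps1. The transferrin receptor gene Tfrc had a log2 difference of 0.54 (SE 0.33), the iron exporter gene Slc40a1 0.54 (SE 0.50), Ncoa4, which carries ferritin to degradation, -0.21 (SE 0.20), and the iron sensors Aco1 and Ireb2 -0.40 (SE 0.28) and 0.03 (SE 0.29). None of these 5 passed the threshold.

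The ferroptosis list was not called by camera (19 genes, median 0.11, adjusted p = 0.126), but fry, which makes no comparison with other genes, called it (adjusted p = 0.0446, where all alternatives gave 0.0446 to 0.456). Without control 3 the median was -0.047. Over all genes 1 rose (Hmox1), 0 fell and 18 did not pass, and adjusted over the list alone 2 rose and 17 did not pass. The second was Alox5, a lipoxygenase, named after its values were seen, at 0 in control and 12.6 ± 6.23 FPKM in Fth1-deleted libraries (adjusted p = 0.0667). Gpx4, which reduces lipid peroxides, was at 359 ± 46.9 and 407 ± 39.9 (adjusted p = 0.731), and its value is uncertain since 73.7% of its length is 99.7% identical to the pseudogene Gpx4-ps2. Heme synthesis (13 genes, median 0.22, or 0.057 to 0.32 with 1 library left out, adjusted p = 0.117) was not called. It was called without control 1 (median 0.32), with the Y-linked term (0.38) and among the libraries with low mt-Co2 (0.35). Iron-sulfur cluster assembly (22 genes, median 0.01, or -0.0076 without control 2, adjusted p = 0.452) was not called. Of either list 0 members passed over all genes or adjusted over the list alone. Cpox was at 33.8 ± 13.0 and 67.7 ± 17.4, Alad at 31.4 ± 21.6 and 53.4 ± 7.41, Glrx5 at 55.9 ± 14.5 and 98.1 ± 28.6 and Ciapin1 at 33.3 ± 6.76 and 48.4 ± 8.92 FPKM.

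Nuclear genes of the respiratory chain were higher as a group by camera, but their list means per library overlapped between the groups. The exact permutation p was 0.143 for complexes III, IV and V, 0.229 for complex I and 0.314 for the TCA cycle, which overlapped as well. The list of complexes III, IV and V had a median of 0.30, or 0.17 without control 2, with 31 of 36 positive (camera adjusted p = 8.37e-06; adjusted p = 0.360 with an estimated correlation). No gene of the list passed over all genes, and adjusted over the list alone 1 rose, 0 fell and 35 did not pass: Uqcrq, a subunit of complex III, at 51.7 ± 14.0 and 118 ± 29.3 FPKM. Uqcr11 was at 84.7 ± 32.8 and 149 ± 14.8. The complex I list had a median of 0.34, with 32 of 37 positive and a call that ended without control 2 at a median of 0.25 (camera adjusted p = 0.000235; adjusted p = 0.360 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Ndufa7 was at 182 ± 9.81 and 108 ± 32.9, and Ndufs5 at 37.3 ± 13.2 and 70.3 ± 30.8. The TCA cycle list was higher by a median of 0.22 over 22 genes, or 0.047 without control 2 and 0.34 without control 1 (camera adjusted p = 0.0123; adjusted p = 0.462 with an estimated correlation) with 0 members past the threshold in either adjustment. Idh3a was at 38.3 ± 15.7 and 60.5 ± 8.31 and Idh2 at 201 ± 21 and 264 ± 21.7 FPKM. The glycolysis list was higher by a median of 0.18 over 17 genes, or 0.087 without control 2 (camera adjusted p = 0.0272; adjusted p = 0.306 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 2 rose, 1 fell and 14 did not pass. Those that rose were Hk2 (14.2 ± 3.05 and 34.7 ± 12.0), which commits glucose to the cell, and Aldoa (307 ± 20.1 and 450 ± 67.2), and the one that fell was Ldhb (113 ± 63.3 and 42.0 ± 18.0), which shares 76.8% of its length with the pseudogene Gm5514 at 98% identity. The calls of TCA cycle and glycolysis ended under TPM, under quantile normalization and without control 2. That of TCA cycle also ended without Fth1-deleted 4 (median 0.16) and with the replicate block, and that of glycolysis without a trend.

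The mitochondrially encoded list was not called (13 genes, median -0.14, adjusted p = 0.855), with 0 members past the threshold in either adjustment. mt-Nd6 was at 193 ± 20.3 and 233 ± 34.8 and mt-Nd2 at 355 ± 6.30 and 430 ± 90.2 FPKM. A block of 5 of these genes, mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l, was 29.5 to 70.05-fold higher in control 1 and Fth1-deleted 3 than in the other 5 libraries, and mt-Co2 was at 2468 and 1750 FPKM in that pair of libraries and at 60.8 to 77.2 in the others. These 5 genes have near-identical nuclear copies, so their values are uncertain.

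**Figure D4:**
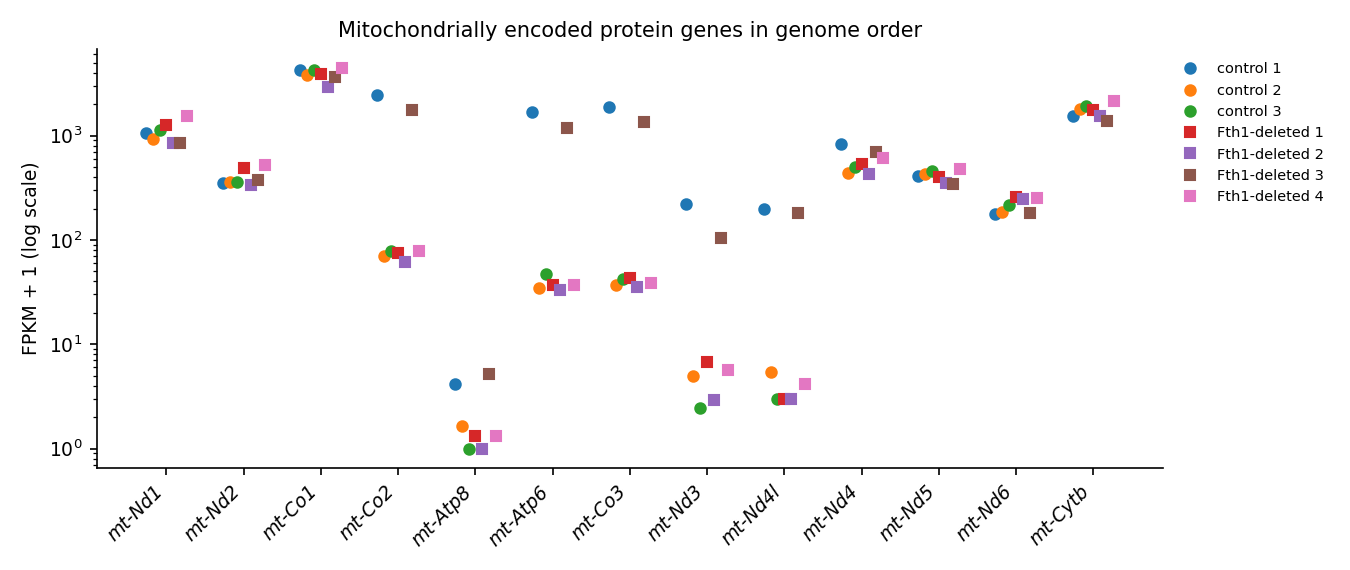
FPKM + 1 (log axis) of the 13 mitochondrially encoded protein genes in genome order, in each of the 3 control (circles) and 4 Fth1-deleted (squares) libraries. In control 1 and Fth1-deleted 3, 5 genes are 29.5 to 70.05-fold above the other 5 libraries, while the other genes above 50 FPKM have ratios of 0.778 to 1.52.

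The unfolded protein response list was higher with a median of 0.28 and 16 of 18 positive (camera adjusted p = 9.39e-05; adjusted p = 0.296 with an estimated correlation). None passed over all genes, and adjusted over the list alone 1 rose, 0 fell and 17 did not pass: Sdf2l1, a chaperone of the endoplasmic reticulum, at 26.8 ± 20.3 and 80.5 ± 16.0 FPKM. Manf was at 51.3 ± 24.3 and 88.6 ± 9.71. The integrated stress response list was not called (23 genes, median 0.28, or 0.092 to 0.35 with 1 library left out, adjusted p = 0.162), and 0 members passed over all genes or adjusted over the list alone. Mthfd2 was at 14.5 ± 9.95 and 45.2 ± 17.9 and Nars at 137 ± 15.6 and 94.4 ± 10.3. Lists of hypoxia targets (18 genes, median -0.07, adjusted p = 0.647), cholesterol and fatty acid synthesis (23 genes, median -0.06, adjusted p = 0.542), lysosome and autophagy (28 genes, median -0.09, adjusted p = 0.782), NF-kB and inflammatory cytokines (15 genes, median -0.19, adjusted p = 0.115, but called without control 1 at a median of -0.42) and interferon response (30 genes, adjusted p = 0.983) were not called. None of their members passed over all genes or adjusted over the list alone. NF-kB was also called lower in settings chosen after seeing the data. These were the ribosomal RNA covariate (median -0.70), the Y-linked term (-0.48) and the libraries with low mt-Co2 (-0.48). Among the 5 libraries with high ribosomal RNA, with control 2 as the only control, its median was -0.72. The signs of the interferon list differ, with a median of -0.13, a mean of 0.15 and a camera direction of down; Gbp2 was at 43.7 ± 11.5 and 18.8 ± 6.21 and Oas2 at 5.32 ± 1.90 and 15.7 ± 4.46 FPKM. Of the others, Ndrg1 was at 119 ± 28.2 and 75.9 ± 31.7, Scd1 at 4.32 ± 1.77 and 0.214 ± 0.429, Idi1 at 38.5 ± 14.7 and 23.7 ± 24.8, Map1lc3b at 113 ± 28.0 and 75.7 ± 7.51, Ctsd at 95.1 ± 11.7 and 126 ± 24.5, Traf1 at 15.7 ± 9.30 and 3.22 ± 0.303 and Nfkbia at 108 ± 33.6 and 62.4 ± 11.8.

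Lists of markers of other cells were measured in the same way. The megakaryocyte and platelet list had a mean log2(FPKM + 1) of 5.11 in control and 4.71 in Fth1-deleted libraries. Its genes were thus already read in control HSCs, and their lower values cannot be told apart from those of the stem cell list. The megakaryocyte and platelet list was not called (16 genes, median -0.30, adjusted p = 0.117), except without control 2 (median -0.35) and with the replicate block. Over all genes 0 passed, and adjusted over the list alone 0 rose, 2 fell and 14 did not pass: Clu (36.4 ± 12.1 and 7.22 ± 5.47 FPKM) and the platelet granule protein gene Mmrn1 (70.1 ± 17.3 and 29.9 ± 10.6). The monocyte, macrophage and dendritic cell list was not called (19 genes, median 0.19, adjusted p = 0.254). It was called without Fth1-deleted 2 (median 0.19) and with arrayWeights (0.43). Its median was -0.24 without Fth1-deleted 1 and -0.17 without control 2. No gene of the list passed over all genes, and adjusted over the list alone 1 rose and 18 did not pass: the complement gene C1qb, at 2.82 ± 3.32 and 20.5 ± 9.12. Cd68 was at 8.70 ± 4.82 and 21.9 ± 2.73. The erythroid list was not called (18 genes, median 0.24, adjusted p = 0.115), but it was called without control 1 (median 0.68) and without Fth1-deleted 2 (0.56). It was also called with the ribosomal RNA covariate (0.48), the Y-linked term (0.58) and among the libraries with low mt-Co2 (0.56), settings chosen after seeing the data. Among the 5 libraries with high ribosomal RNA, with control 2 as the only control, its median was 0.58. The erythroid list had 0 members past the threshold in either adjustment, with Epor at 34.3 ± 20.2 and 56.7 ± 6.05 and Hbb-bt at 14.9 ± 15.4 and 52.2 ± 33.6. The T and NK cell list (8 genes, median -0.90, or -1.04 with genes at their bound, adjusted p = 0.647) had 1 gene that rose adjusted over the list alone, Nkg7 (51.7 ± 47.8 and 119 ± 29.9), 7 that did not pass, and 0 over all genes. Cd247 was at 2.79 ± 1.37 in control and 0 in Fth1-deleted libraries, at least 23.0-fold lower against 3 reads per library. Its value is uncertain, since 72.3% of its length is 100% identical to a transcript of Pou2f1. The endothelial and stromal list (7 genes, adjusted p = 0.647) had 0 members past the threshold in either adjustment, and its signs differ, with a median of -0.13 (-0.39 to 0.20 with 1 library left out), a mean of 0.16 and a camera direction of up. Col1a2 was at 7.74 ± 3.43 and 2.65 ± 1.80 and Pdgfrb at 0.908 ± 0.787 and 5.24 ± 3.91. The handling list of immediate early and heat shock genes (17 genes, median 0.19, adjusted p = 0.565) was not called. Its median was -0.088 to 0.49 with 1 library left out. It was called without Fth1-deleted 4 (median 0.39) and with the replicate block. It had 0 members past the threshold over all genes, and adjusted over the list alone 2 rose, 1 fell and 14 did not pass. Hsp90aa1, which shares 68.7% of its length with the pseudogene Gm12346 at 99.5% identity, and Hsph1, named after its values were seen, had log2 differences of 0.54 (SE 0.15) and 0.87 (SE 0.27), and Egr1 of -1.51 (SE 0.41).

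Some measures of library composition differed between the groups too. The ribosomal RNA gene CT010467.1 took 0.0244%, 0.983% and 0.0140% of reads in control and 1.21%, 1.29%, 1.33% and 1.34% in Fth1-deleted libraries (exact permutation p = 0.0286, the smallest possible). The 10 most abundant genes took 4.67% ± 0.394 of reads in control and 5.34% ± 0.280 in Fth1-deleted libraries (exact permutation p = 0.0286). The low libraries for CT010467.1 were both control. Among the other 5, with control 2 as the only control, assumed to vary like the others and itself the control with the highest stem cell and the lowest S phase and G2 and M phase means, 43 genes were higher and 176 lower, 4 of them among the 8 called genes. In those libraries 14 lists were higher and 2 lower. Y-linked genes were read in control 2 and in Fth1-deleted 1, 2 and 3, with Ddx3y at 24.6 FPKM in control 2 and at 13.5, 16.5 and 29.2 in the others, and at 0 in control 1, control 3 and Fth1-deleted 4. Xist, the RNA of the inactive X chromosome, was at 142, 42.5 and 89.3 FPKM in the latter 3 libraries and at most 2.25 in the other 4. These values point to male and female libraries spread unevenly over the groups, though the labels do not state sex. With a term for Y-linked reads 7 genes were higher and 10 lower, the 8 called genes among them, and 16 lists were higher and 2 lower. This term rests on control 2 and Fth1-deleted 4, which differ in Y-linked reads from the rest of their groups. It cannot separate sex from other traits of these libraries, such as the ribosomal RNA share of control 2. Among the 5 libraries with low mt-Co2, 0 genes were called by limma (1574 had an unadjusted p under 0.05), and 13 lists were higher and 2 lower. These subsets and the term were chosen after seeing the data.

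**Figure D5:**
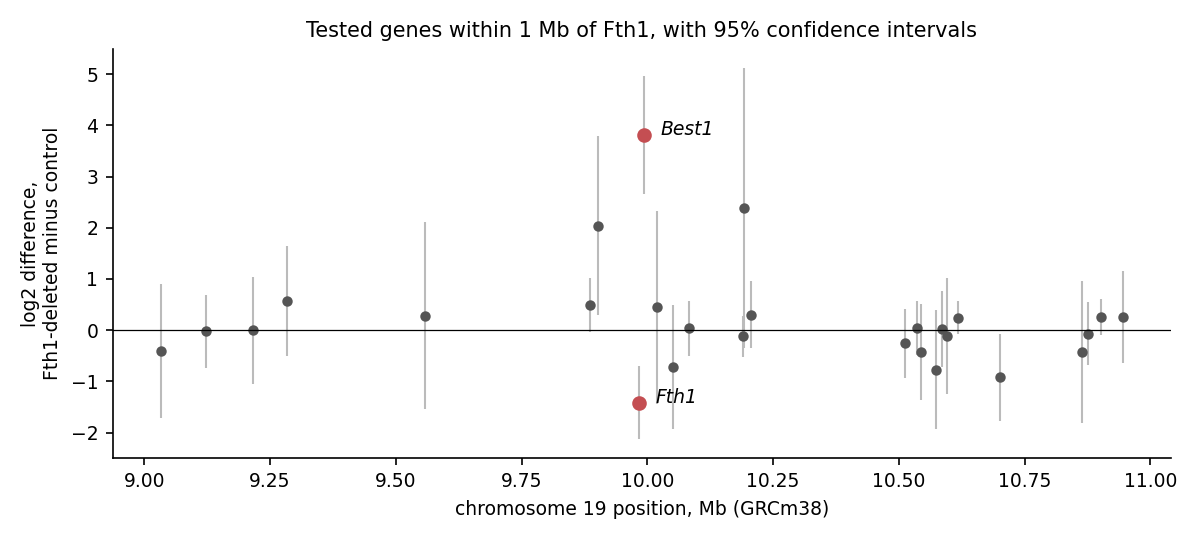
Log2 difference (Fth1-deleted minus control) of each tested gene within 1 Mb of Fth1 on chromosome 19 (position in Mb), with 95% confidence intervals (lines). Best1 (3.82) and Fth1 (-1.42) are marked, and 0 of the other 25 genes passed the threshold (limma, Benjamini-Hochberg).

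Of 13948 genes tested by limma, 1371 (9.83%) had an unadjusted p under 0.05, 683 of them higher and 688 lower, and 24 had an adjusted p under 0.1. The groups did not overlap for 572 higher and 774 lower genes, 9.65% of those tested, where chance gives 5.71% for a single gene. Genes move together between libraries, so the share in 1 split can lie far from that. Other splits of the 7 libraries gave 338 to 1110 genes at an unadjusted limma p under 0.05, so the excess is not a measure of the group effect alone. With camera 14 lists were higher and 1 lower, but with an estimated correlation 0 of 34 were called and 4 had an unadjusted p under 0.05, and directional fry called 1. By the exact permutation test of list means per library, 7 of 34 lists had p under 0.05, and 0 after adjustment over the lists. Each of the 8 called genes lost its call when any 1 of the 7 libraries was left out, and with no filter on low values 0 genes were called (1504 had an unadjusted p under 0.05).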

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

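The tests of mature cells, of progenitors, of run-on transcription, of the read number of Best1, of the splits without the Y-linked one, of the chromosome 19 region, of more mitochondrial RNA and of a differing mitochondrial sequence were chosen only after the result was seen. In the Fth1-deleted group (n = 4), 12 of 102 values tested had a single library far from the other 3. Chance gives about 1 in 20 for independent, normally distributed values. Neighbouring mitochondrial genes moved together here, so the 12 are not separate events. Fth1-deleted 1 was the highest for Cdkn1a (18.8 FPKM, others at most 6.83), Slc40a1 (43.6, others at most 16.9) and Cd68 (26.0, others at most 20.8). Fth1-deleted 2 was the highest for Scd1 (0.857, others at 0) and Fth1-deleted 4 for Ndufs5 (116, others at most 58.1). Fth1-deleted 3 held 7 of the 12 values. It was the lowest for mt-Nd6 (182, others at least 243) and the highest for mt-Atp6 (1188), mt-Co2 (1750), mt-Nd4l (181), mt-Nd3 (104), mt-Co3 (1361) and mt-Atp8 (4.21).

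By camera the stem cell list was lower and the S phase, G2 and M phase and multipotent progenitor lists were higher, calls that are lost with an estimated correlation (adjusted p = 0.296, 0.296, 0.306 and 0.296). More cells of every mature blood type in the sort stay open: the megakaryocyte list (16 tested genes) and the neutrophil list (14 tested genes), with 0 genes held by another list, moved apart by -1.85 in mean log2 value (exact permutation p = 0.0286), but the means in control were 5.11 and 2.55, so that the higher one, like Prtn3 and Lyz2 at 212 and 164 FPKM, would hide a small share. Lower megakaryocyte values also cannot be told apart from the lower stem cell list, so this test does not decide. Ribosomal RNA carry-over that differs between libraries cannot be told apart from the groups: 3 of 3 lists (stem cell, S phase, G2 and M phase) kept direction and call among the 5 libraries with high ribosomal RNA (medians -0.90, 0.59 and 1.06) and with the covariate (-0.90, 0.62 and 1.03), but both rest on control 2, the only control with high ribosomal RNA and the one with the highest stem cell (5.84) and lowest S phase (5.52) and G2 and M phase means (4.50). More multipotent or committed progenitors within the sort, whose markers are not stated, may account for it and cannot be told apart from a changed state of the stem cells after Fth1 deletion: Cd48 had a log2 difference of 1.57 (SE 0.51), and whole-library values do not show whether a few cells or all of them changed. The list of multipotent progenitors (12 tested genes, 0 of them in another list) had camera adjusted p = 0.000854, and Cd34 was at 66.7 FPKM in control and 121 in Fth1-deleted libraries (limma adjusted p = 0.326).

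Best1 was read in all 4 Fth1-deleted libraries and at 0 in control. A rise of the whole chromosome 19 region by as much as Best1 (log2 difference 3.82) is argued against, since the other 25 tested genes within 1 Mb had a median log2 difference of 0.015 (SD 0.74) and 24 of their 95% intervals lay below 3.82, while a smaller change, or one of a few genes such as AC132253.4 and Mir6993 (also at 0 in control, and named after their values were seen), stays open. Chance on and off genes in thin libraries stay open. Best1 had at least 198 reads in each Fth1-deleted library and 0 in control, but its read number was tested only after this pattern was seen. By number, 6 genes were at 0 in control and above 5 FPKM in each Fth1-deleted library. These were Best1, Snord49a, Mypopos, Bok, Alox5 and Bbs5, named after their values were seen. Of the 35 splits 2 held as many, so chance cannot be excluded. The other split with 6 follows the Y-linked reads, with 4 of its genes on chromosome Y, and points to a structure of the samples. The highest of the rest held 3, but leaving out the Y-linked split was chosen after the result was seen and does not decide. Transcription from the altered Fth1 allele running on into Best1 may account for the Best1 reads. It stays open, since the genes end 75 bp apart on opposite strands and gene-level values cannot show joined reads.

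The genes mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l were high in control 1 and Fth1-deleted 3, a pair of libraries from both groups, so that the study's groups give no biological explanation to test. More mitochondrial RNA in this pair is argued against, since the highest ratio to the other 5 libraries was 1.52 among the 7 other mitochondrial protein genes above 50 FPKM (mt-Atp8, at 3.69 FPKM in the pair, had a ratio of 14.2 and is left open). Another counting rule for near-identical genes is argued against, since the median ratio was 0.902 over 227 nuclear genes with a near-identical copy, and 1 of them reached 5-fold. A mitochondrial sequence that differs from the reference, and so from its nuclear copy, may account for it: 5 of 5 of these genes have a copy on chromosome 1 at 98% identity over 80% of their length, against 0 of 8 other genes, of which mt-Co1 (97.6% identical over its length) and mt-Nd4 (100% over 63.6%) had ratios of 1.02 and 1.52. It stays open, since bases of the reads were not analysed here. mt-Atp8 was 14.2-fold higher in the same pair, and no such copy of it was found. Copies were searched among annotated transcripts only, so mt-Atp8 does not decide for or against this contrast.

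All 35 splits of the libraries into 3 and 4 were tested in the same way. For genes higher the real value was 4 and the highest other 2, and for genes lower also 4 and 2. In each case 1 of 35 splits was as large, which is the smallest share possible and is not adjusted over the counts tested. Chance is therefore argued against for the counts of genes but not excluded. For lists higher the real value was 14 and the highest other 14 (control 1, control 2 and Fth1-deleted 2 as the 3), with 2 of 35 splits as large. For lists lower the real value was 1 and the highest other 15 (Fth1-deleted 1, 3 and 4 as the 3, which turns the direction of the comparison), with 30 of 35 splits as large. Chance cannot be excluded for the counts of lists either.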

How the results depend on the processing

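Protein-coding genes alone, the ribosomal RNA covariate, the libraries with high ribosomal RNA, the term for Y-linked reads, the libraries with low mt-Co2 and limma-voom were tests chosen only after the result was seen. Of the results for called genes, 76 kept direction and call and 104 kept direction and lost the call; for called lists these were 323 and 50. Among results not called, 1749 for genes and 418 for lists kept direction and side, 6 and 24 gained a call, and 10 and 31 turned direction. No called gene or list turned direction.

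Counts of called genes (4 higher and 4 lower) became 0 and 0 by limma with no filter, where 19119 genes were tested, with the replicate block, and among the 5 libraries with low mt-Co2 (1504, 987 and 1574 genes at an unadjusted p under 0.05). They became 10 and 7 without a trend (3 of the 8 genes shared), 5 and 2 with protein-coding genes alone, where the non-coding genes are not tested, 17 and 6 with the ribosomal RNA covariate (1 shared), 43 and 176 in the libraries with high ribosomal RNA (4 shared), 7 and 10 with the Y-linked term (8 shared), 0 and 5 with limma-voom (4 shared), and 4 and 2 with treat. The remaining settings gave 3 or 4 higher and 3 or 4 lower. Lists (14 higher, 1 lower) became 0 and 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 1 and 0 with fry (10 at an unadjusted p under 0.05), and elsewhere 12 to 16 were higher. There were 2 lower with the block, the covariate, the high ribosomal RNA libraries, the Y-linked term and the low mt-Co2 libraries. TPM shifted the median of all genes from -0.02 to -0.09. The Fth1 difference ranged from -1.74 with the Y-linked term (adjusted p = 0.0491, 0.0491 to 0.684 over all alternatives) to -1.09 with the block, below 0 in all. The block rests on shared numbers only: correlations of residuals for libraries with the same number were 0.009, 0.061 and -0.037, with no sign of pairing, and the block leaves 2 residual degrees of freedom. For other settings the cause was not tested.

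With each library left out in turn, genes higher ranged from 0 to 3, genes lower from 0 to 1, lists higher from 11 to 16, lists lower from 1 to 2 and the Fth1 difference from -1.63 to -1.09. Each of the 7 libraries ended the call of all 8 genes when left out (1021 to 1644 genes at an unadjusted p under 0.05 by limma), and without control 2 the 3 higher and 1 lower genes shared 0 with these 8. Hmox1 then had adjusted p of 0.116 to 0.281 and differences of 1.95 to 2.31. Fewer libraries leave fewer degrees of freedom. Median differences of lists ranged from -0.74 to -0.44 for stem cell genes, 0.28 to 0.54 for S phase and 0.27 (without control 2) to 0.83 for G2 and M phase. Without control 2 they were also lower for DNA damage repair (0.12), complexes III, IV and V (0.17), TCA cycle (0.047) and glycolysis (0.087). Without control 2 the adjusted p was 0.0642 for complex I, 0.360 for TCA cycle, 0.372 for glycolysis and 0.0521 for mast cells, and lists of p53 targets (0.0274) and megakaryocytes (0.0459) passed. Mast cells also lost the call without control 3 (0.114), Fth1-deleted 3 (0.126) and Fth1-deleted 4 (0.115), and TCA cycle without Fth1-deleted 4 (0.123). Among the 5 libraries with low mt-Co2 the adjusted p was 0.0661 for multipotent progenitors and 0.0849 for neutrophils. Without control 1, NF-kB (0.0118), erythroid (0.00916) and heme synthesis (0.0315) passed; without Fth1-deleted 2, erythroid (0.00625) and monocytes (0.0410); and without Fth1-deleted 4, the handling list (0.0357). Over all alternatives the adjusted p ranged from 0.0118 to 0.565 for NF-kB, 0.00480 to 0.649 for erythroid, 0.0233 to 0.454 for heme synthesis, 0.0274 to 0.899 for p53 targets, 0.0459 to 0.920 for megakaryocytes, 0.0404 to 0.722 for monocytes, 0.0357 to 1.00 for handling, 0.00834 to 0.296 for mast cells, 0.000159 to 0.296 for multipotent progenitors, 0.000349 to 0.296 for neutrophils, 2.51e-05 to 0.462 for TCA cycle, 0.00514 to 0.372 for glycolysis and 3.97e-07 to 0.360 for complex I.

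Results not called turned direction as follows (for lists camera's direction, given with the median). Left-out ranges were -0.45 to 0.16 for Cdkn1c, -0.058 to 0.13 for Ireb2, -0.81 to 0.10 for Mecom, -0.15 to 0.78 for Slamf1, -0.21 to -0.044 for interferon, -0.10 to 0.035 for lysosome, -0.21 to 0.26 for mitochondrially encoded genes, -0.24 to 0.57 for monocytes and -1.20 to -0.35 for T and NK cells. Cdkn1c was at 0.16 with the block, and Ireb2 at -0.043 under TPM and -0.030 with arrayWeights. Interferon was at -0.12 with pseudocount 5, -0.10 with quantile normalization, -0.13 without a trend, -0.073 with arrayWeights and -0.045 with the Y-linked term. With the ribosomal RNA covariate, mitochondrially encoded genes were at 0.34, lysosome at 0.047, megakaryocytes at -0.25, T and NK cells at 0.50 and handling at -0.32. In the libraries with high ribosomal RNA they were at 0.31, lysosome at 0.020, T and NK cells at 0.35 and handling at -0.32. With the Y-linked term mitochondrially encoded genes were at -0.055, T and NK cells at -0.53 and handling at -0.37. In the libraries with low mt-Co2 mitochondrially encoded genes were at -0.057, T and NK cells at 0.020, endothelial and stromal genes at -0.0596 and handling at -0.15. Medians also changed sign with camera's direction kept. Iron handling was at -0.12 with the covariate (p53 targets at -0.0078), -0.051 with high ribosomal RNA and -0.041 with the Y-linked term. Iron-sulfur clusters were at -0.062 under TPM. With no filter T and NK cells were at 0.051, endothelial and stromal genes at 0.26 (0.15 with limma-voom). Left-out ranges were -0.063 to 0.22 for iron handling, -0.047 to 0.15 for ferroptosis and -0.088 to 0.49 for handling. The causes were not tested. At this depth 3 reads of a gene of 1 kb make an FPKM of 0.194 to 0.249, the bound used for a group at 0, and in simulated data 13.6% of 2-fold changes were called.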

Other observations

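The gene families and single genes here, and the tests on them, were chosen only after the result was seen. Histocompatibility genes, which present peptides at the cell surface, were lower as a family in Fth1-deleted HSCs: 21 of 22 had negative log2 differences with a median of -0.53 (camera adjusted p = 5.75e-07 over 22 families; adjusted p = 0.298 with an estimated correlation). The median was -0.61 under TPM, -0.51 with size factors and -0.57 with quantile normalization. No member passed over all genes, and adjusted over the family alone H2-Q7, H2-T23, H2-Q4 and H2-Q6 fell. Of the 22 families tested, 11 were called by camera and 0 with an estimated correlation, where the adjusted p ranged from 0.298 to 0.891.

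Of the other called families 9 were higher and 1 was lower. The mitochondrial ribosomal proteins had a median log2 difference of 0.26 with 59 of 77 positive (adjusted p = 0.00220; adjusted p = 0.467 with an estimated correlation). The chaperonin subunits had 8 of 8 positive with a median of 0.24 (adjusted p = 0.0133; 0.479 with an estimated correlation), and the proteasome subunits 27 of 39 with a median of 0.19 (adjusted p = 0.00252; 0.479 with an estimated correlation). The heat shock proteins of 70 and 90 kDa had 11 of 14 positive with a median of 0.40 (adjusted p = 0.00274; 0.446 with an estimated correlation), with Hspa8 at 2078 ± 55.8 and 3031 ± 389 FPKM. The replication-dependent histones had 26 of 34 positive with a median of 0.59 (adjusted p = 0.00274; 0.467 with an estimated correlation). The small nucleolar RNA genes had 19 of 24 positive with a median of 0.97 (adjusted p = 0.00220, and 0.446 with an estimated correlation). The share of ribosomal RNA reads was higher in Fth1-deleted libraries. Whether the histone and small nucleolar RNA families follow that share was not tested. The remaining called families were the aminoacyl-tRNA synthetases, mitochondrial import and spliceosome proteins, with medians of 0.19, 0.26 and 0.45, and the zinc finger genes, with a median of -0.19. Camera with an estimated correlation gave them adjusted p values of 0.446, 0.467, 0.517 and 0.467. The median of each of these 10 families kept its sign under TPM, size factors and quantile normalization, but it was 0.11 under TPM for the proteasome and for the aminoacyl-tRNA synthetases, and 0.13 with quantile normalization for the chaperonins. Related families were not called: cytosolic ribosomal proteins (84 genes, median -0.08, adjusted p = 0.542), translation initiation factors (53 genes, median 0.06, adjusted p = 0.212) and DnaJ cochaperones (39 genes, median -0.13, adjusted p = 0.642).

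Some single genes stood near the called ones. Mt1, a metal-binding metallothionein, was at 30.3 ± 18.8 FPKM in control and 258 ± 173 in Fth1-deleted libraries (limma adjusted p = 0.110, and 0.0167 with the term for Y-linked reads, where its log2 difference was 3.59). Arrdc4, a relative of Txnip, was at 38.5 ± 6.84 and 15.2 ± 1.92 FPKM (adjusted p = 0.193). Also called with that term, which rests on control 2 and Fth1-deleted 4, were Obsl1, Cbx7, Trim47, Egr1, Tinagl1 and Fth1, which were lower, and Lgals1 and Psmg4, which were higher. With the term, the lists of heme synthesis (adjusted p = 0.0333) and erythroid genes (adjusted p = 0.00480) were higher and NF-kB genes (adjusted p = 0.0152) lower by camera, where all alternatives gave 0.0233 to 0.454, 0.00480 to 0.649 and 0.0118 to 0.565.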
